A study of Daphnia magna with 45 samples.

How the data were processed

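RNA was sequenced from whole bodies of female Daphnia magna, a freshwater crustacean, of the strain Xinb3. Animals aged 5 days were kept in groups of 20 in 35 mL of solution, and libraries were made from 500 ng of total RNA with a stranded mRNA kit, per the labels' protocols. The solutions held propranolol at 1 mg/L, propranolol at 4 mg/L, isoprenaline at 100 mg/L, or a mixture of propranolol at 1 mg/L and isoprenaline at 100 mg/L, beside a control. Propranolol is a blocker of beta-adrenergic receptors and isoprenaline activates them.

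The deposited values are CPM, the reads of an ID scaled to a library total of 1000000. The submitters' processing notes name Trim Galore 0.3.2, Bowtie2 2.1.0, HTSeq and edgeR, and the genome build and annotation are not given in the sources used here. Each CPM column of the deposited table sums to 1000000, and the table holds 19159 rows, each with its own ID. Every value was a whole multiple of the smallest step of its library, so whole reads were recovered for 100% of 862155 values within a tolerance of 0.01 read. The recovered totals ran from 13.5 to 43.7 M reads per library, with a median of 19.1 M. A floor of 3 reads then stands for 0.069 to 0.22 CPM. Exact binomial intervals at the 95% level and these floors cover counting error only, since reads from amplified libraries are not independent molecules.

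All 45 libraries were assigned to 16 groups of exposure and hour from their titles. There were 14 groups of 3 libraries, 1 group of 2 and 1 group of 1. None of the 45 libraries was labelled replicate 3 of propranolol 4 mg/L at 6 h. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The 43 pairs of libraries of the same group differed by far more than sampling noise (chi-square per degree of freedom of 17.4 to 640.4), so none was counted as a duplicate.

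The main test was limma 3.58.1 (trend and robust options, R 4.3.3) on log2(CPM + 1), with the means of all 16 groups in a shared fit with 29 residual degrees of freedom, and Benjamini-Hochberg adjustment within each of 28 comparisons. Calls are IDs with an adjusted p under 0.05. Fold changes are on the log2(CPM + 1) scale, which understates the change of low IDs. The planned filter kept IDs with at least 1 CPM in at least 3 libraries. The deposited table had already passed it, with 19159 rows kept. The groups, tests, alternatives and naming rule were fixed before the data were examined.

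Beside the main test, every comparison was repeated with a pseudocount of 0.25, with no filter, a fit of only the groups compared, the replicate number as a block, scaling by the median log ratio, edgeR 4.0.16 (quasi-likelihood test) on the recovered reads, and leaving out each library in turn. Added after seeing the data were 1 surrogate variable (sva 3.50.0), a mean of at least 5 CPM, direct contrasts of isoprenaline and of the mixture with propranolol 4 mg/L, the difference between the effects of propranolol 4 mg/L at 6 and 1 h, a contrast of these 3 exposures with control and propranolol 1 mg/L, and counts of shared calls.

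The labels do not say that replicate numbers pair libraries. The deviations of same-numbered libraries from their group means correlated above 0.1 in every pair in 4 of the 18 comparisons within an hour that had 3 pairs. These were propranolol 1 mg/L against control at 1, 3 and 6 h (lowest r of 0.22, 0.164 and 0.389) and the mixture against isoprenaline at 6 h (lowest r of 0.149). With the replicate number as a block these 4 comparisons had 0 calls, as without it. Comparisons of propranolol 4 mg/L at 6 h had 2 pairs and were not counted. Their r were 0.716 and 0.545 with control, and 0.826 and 0.731 with propranolol 1 mg/L.

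None of the IDs matched the reference table of 28335 genes, which held no product text (0 IDs matched). All 26 gene lists fixed beforehand were therefore void, and genes are given by ID. The naming rule asked for the IDs with the largest change among those called, with every exposed library on the same side of every control library and a mean of at least 5 CPM. Without names it allowed 2 IDs that rose and 2 that fell in all. They were taken over the 11 comparisons with control, from 1221 candidate results, and that ranking over all 11 was settled only once the table was at hand, before the values were seen. Any other ID named was chosen after its values were seen.

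The steps were tested on simulated data with the real means and totals, for isoprenaline against control at 6 h over 19159 IDs. Of the IDs changed 2-fold, limma recovered 37.3% and edgeR 34.3%. At 4-fold both recovered 77.6%, and at 8-fold limma recovered 90.9% and edgeR 95.5%. There were 14 false calls with limma and 8 with edgeR. The simulation drew each ID independently and so lacks the structure between real libraries described in the closing section.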

Results

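Messenger RNA of whole Daphnia magna was measured in 45 libraries of animals exposed to a blocker of beta-adrenergic receptors (propranolol, 1 or 4 mg/L), an activator (isoprenaline, 100 mg/L), their mixture (1 and 100 mg/L) or neither. Control and propranolol 1 mg/L were sampled at 1, 3, 6 and 24 h, propranolol 4 mg/L at 1, 6 and 24 h, and isoprenaline and the mixture at 1 and 6 h, with 3 libraries each except 2 for propranolol 4 mg/L at 6 h. A control at 0 h had 1 library and entered no comparison. Totals ran from 13.5 to 43.7 M reads, and between 13 and 441 of the 19159 IDs were at 0 in a library. The series addresses how these compounds change gene expression alongside the heart. Libraries of the same group differed widely: Pearson correlations of log2 CPM across IDs, which are not independent replicates, ran from 0.762 to 0.991. The 10 most abundant IDs took 8.65% to 25.6% of the reads of a library.

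**Figure D1:**
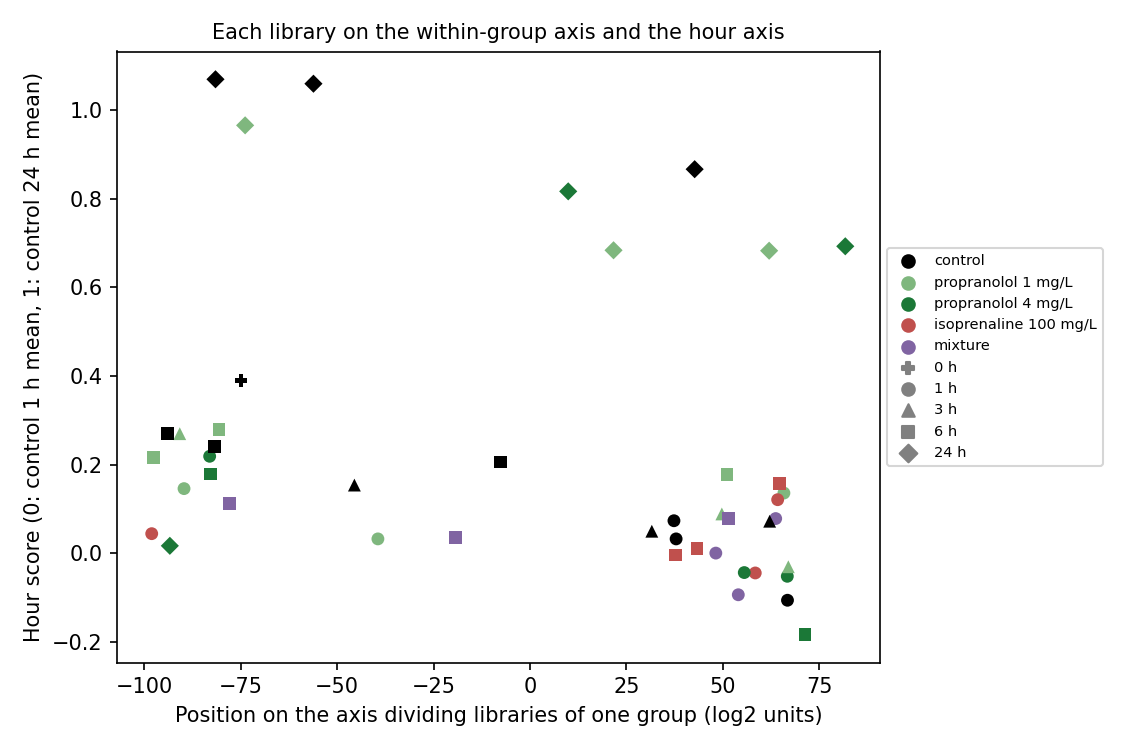
Each point is a library, by its position on the first component of the deviations from the group means (x axis, log2 CPM units) and by an hour score (y axis, no unit) that is 0 at the mean of the control at 1 h and 1 at that at 24 h, with colour for exposure and shape for hour. Of the 24 h libraries, 8 score between 0.683 and 1.07 and replicate 1 of propranolol 4 mg/L scores 0.0169.

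Unexposed animals differed between 1 and 24 h. At 24 h, 1454 IDs were higher and 1012 lower than at 1 h, with median changes of 0.99 and -1.65 on the log2 scale. Dapma7bEVm009664t1 went from 74.1 ± 31.4 CPM (SD, n = 3) to 0.157 ± 0.184 CPM (SD, n = 3), and Dapma7bEVm027893t1 from 293.1 ± 105.7 CPM to 29.6 ± 22.99 CPM (SD, n = 3 each). Both falls passed the limma test, with log2 changes of -5.94 (SE 0.941, adjusted p 0.000116) and -3.84 (SE 0.795, adjusted p 0.00198). Dapma7bEVm016578t1 and Dapma7bEVm021384t1 rose by 2.97 (SE 0.999) and 2.84 (SE 0.957), each with a limma adjusted p of 0.0464, but edgeR gave adjusted p of 0.139 and 0.0937, and with libraries left out in turn both passed only without replicate 2 at 1 h (adjusted p up to 0.191 and 0.233 in the other 5 of 6 fits). Between 1 and 6 h, limma and edgeR each called 1 ID in the control, although 4181 (limma) and 4037 (edgeR) had an unadjusted p under 0.05. The balance of directions at 24 h depended on the setting: edgeR called 1085 higher and 1170 lower, and without replicate 1 of the control at 1 h there were 351 higher and 459 lower. The 24 h count was 1600 and 1638 without replicates 2 and 3 at 1 h, 1183 and 1288 without replicates 1 and 3 at 24 h, and 5177 with 1 surrogate variable. With only the compared groups in the fit the 6 h count was 752 and the fall of Dapma7bEVm027893t1 missed the threshold (adjusted p 0.0537), and without replicate 1 at 6 h the 6 h count was 69.

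Propranolol at 1 mg/L gave no call against control at 1, 3 or 6 h. Unadjusted p under 0.05 was met by 64, 923 and 623 IDs with limma and by 123, 591 and 629 with edgeR, and edgeR also called 0. At 24 h limma called 3 IDs, all lower than control with a median log2 change of -2.25, and edgeR called 0 (554 unadjusted). With only the compared groups in the fit there were 0 calls at 24 h, and 0 without control replicate 1 or 2 or exposed replicate 2 or 3, and 5 (2 higher, 3 lower) without exposed replicate 1. The 6 h count was 3 without control replicate 3. The 4 named IDs did not pass either test at any hour at this dose. Dapma7bEVm016578t1 was at 211 ± 178.7 CPM at 6 h against 293 ± 245 CPM in the control (SD, n = 3 each), a log2 difference of -0.55 (SE 0.999). The median SE of a log2 difference over all IDs was 0.279, which limits the size of difference that could be seen.

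Propranolol at 4 mg/L gave 2 calls at 1 h, both higher than control, but 0 with only the compared groups in the fit and 0 or 1 in each of 6 fits with a library left out. At 6 h, 18 IDs were higher and 736 lower, with median log2 changes of 1.06 and -1.16. At 24 h, 94 were higher and 214 lower, with median changes of 1.21 and -1.40. At 6 h Dapma7bEVm016578t1 was at 0.414 ± 0.142 CPM (SD, n = 2) against 293 ± 245 CPM in the control (SD, n = 3), a limma log2 change of -7.28 (SE 1.12, adjusted p 0.000868). From pooled reads, 15 against 17040, its share was 705-fold lower (427 to 1260, counting error only). Without control replicate 2, which held 10567 of the control reads, it was 401-fold lower. A fall of this ID means lower than the control of that hour, not a fall over time. It was at 0.1 CPM in the single 0 h library. At 1 h it was at 0.135 CPM in propranolol 4 mg/L, 0.206 in isoprenaline and 0.0798 in the mixture (means, n = 3 each). The control was at 22.66 ± 28.11 CPM at 1 h (SD, n = 3).

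Dapma7bEVm021384t1 changed with it, by -6.02 (SE 1.07, limma adjusted p 0.00262) at 6 h and -4.78 (SE 0.957, limma adjusted p 0.00918) at 24 h, when Dapma7bEVm016578t1 was changed by -6.30 (SE 0.999, limma adjusted p 0.0015). The 2 named rises were at 24 h. Dapma7bEVm009664t1 was at 33.9 ± 38.6 CPM against 0.157 ± 0.184 CPM in the control (SD, n = 3 each), a log2 change of 3.67 (SE 0.941, limma adjusted p 0.039), with 8 reads in all in the control libraries. Dapma7bEVm027893t1 was at 291.4 ± 355.1 CPM against 29.6 ± 22.99 CPM (SD, n = 3 each), a log2 change of 3.08 (SE 0.795, limma adjusted p 0.0398). Replicate 1, the library with an hour score of 0.0169, held 14065 of the 20574 reads of Dapma7bEVm027893t1 in this group (699.8 CPM, against 119.2 and 55.23), and without it the ratio of shares from pooled reads was 3.38 in place of 8.22. It also held 1532 of the 2629 reads of Dapma7bEVm009664t1, with a ratio of 114 without it in place of 210 (106 to 487, counting error only). Without control replicate 1 the ratio of Dapma7bEVm009664t1 was 594. These are the IDs that fell between 1 and 24 h in the control. With libraries left out in turn the rise of Dapma7bEVm009664t1 missed the threshold in 5 of 6 fits, all but that without replicate 3 (log2 changes of 2.46 to 5.28, adjusted p up to 0.322). That of Dapma7bEVm027893t1 missed it in 4 of 6, all but those without replicate 3 and without control replicate 2 (1.94 to 3.87, adjusted p up to 0.326). Without replicate 1 at 6 h neither fall passed (adjusted p 0.0798 for Dapma7bEVm016578t1 and 0.214 for Dapma7bEVm021384t1), and at 24 h Dapma7bEVm021384t1 missed the threshold without replicate 1 (0.0549) and without control replicate 1 (0.0527).

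The share of lower calls for propranolol 4 mg/L depended on the scaling. Of the 6 h calls 97.6% were lower, against 85.7% with median log-ratio scaling and 72.6% with edgeR, and the median log2 change of all IDs was -0.124 as deposited and 0.0082 after scaling. Of the 24 h calls 69.5% were lower, against 58.9% and 42.2%, and 48.1% without replicate 2. edgeR called 101 higher and 267 lower at 6 h and 334 higher and 244 lower at 24 h, and 1 at 1 h. With only the compared groups in the fit there were 0 calls at 6 h and 6 at 24 h, none of the 4 named IDs passed at 6 h, and both rises at 24 h missed the threshold (adjusted p 0.566 and 0.602). Calls at 6 h numbered 2 without replicate 1, 1938 without replicate 2, 487 without control replicate 2 and 301 without control replicate 3, and at 24 h 26 without replicate 1, 605 without replicate 3 and 40 without control replicate 1.

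**Figure D2:**
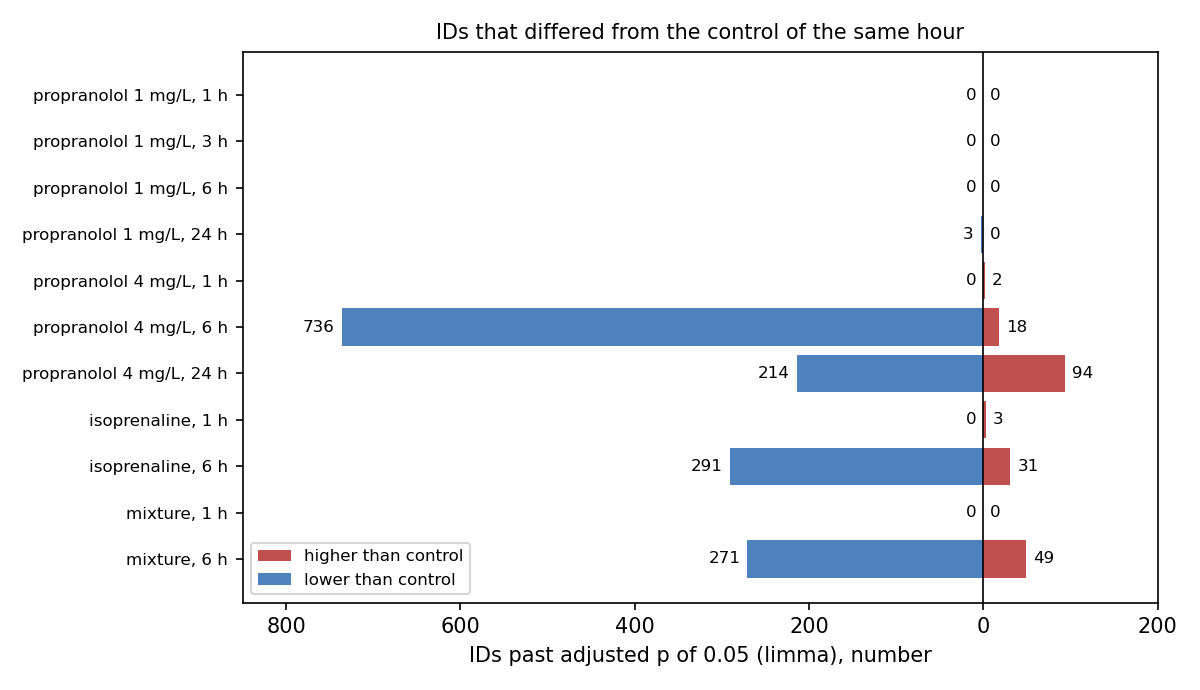
Bars give the number of IDs past a limma adjusted p of 0.05 for each exposure and hour against the control of the same hour, to the right for higher and to the left for lower than control. Propranolol 4 mg/L at 6 h has 736 lower and 18 higher calls, a count that depends on sharing the spread over all groups, and propranolol 1 mg/L has 0 to 3.

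Isoprenaline gave 322 calls at 6 h. At 1 h it gave 3, all higher than control (2 higher and 1 lower with a pseudocount of 0.25), but 0 with only the compared groups in the fit and 0 or 1 in each of 6 fits with a library left out. At 6 h 31 IDs were higher and 291 lower, with median log2 changes of 0.81 and -1.54. Dapma7bEVm016578t1 was at 0.182 ± 0.0937 CPM against 293 ± 245 CPM in the control (SD, n = 3 each), a log2 change of -7.54 (SE 0.999, limma adjusted p 0.000316). With 10 reads against 17040, its share was 1670-fold lower (906 to 3480, counting error only). Without control replicate 2, which held 10567 of the control reads, it was 948-fold lower. This again is against the control of that hour: with isoprenaline the ID was already at 0.206 CPM at 1 h, so a fall over time is not shown. Of the 3 isoprenaline libraries 2 held 3 reads or fewer. Dapma7bEVm021384t1 was at 2.90 ± 0.857 CPM against 370 ± 292.6 CPM (SD, n = 3 each), a log2 change of -6.24 (SE 0.957, limma adjusted p 0.000906). edgeR called 1 ID at 1 h and 308 at 6 h. The 6 h count was 2082 with only the compared groups in the fit, 75 with 1 surrogate variable and 187 at a mean of at least 5 CPM. The mostly lower direction was less marked with only the compared groups (959 higher, 1123 lower) and without control replicate 1 (584 higher, 785 lower). Without control replicates 1, 2 and 3 in turn the count was 1369, 8 and 49, and without isoprenaline replicates 1, 2 and 3 it was 45, 55 and 40.

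The mixture gave no call at 1 h (621 IDs unadjusted with limma, 760 with edgeR, which also called 0) and 320 at 6 h. At 6 h 49 IDs were higher and 271 lower than control, with median log2 changes of 0.70 and -1.44. Dapma7bEVm016578t1 was at 0.301 ± 0.0396 CPM (SD, n = 3) and Dapma7bEVm021384t1 at 4.21 ± 1.34 CPM (SD, n = 3), log2 changes of -7.40 (SE 0.999, limma adjusted p 0.000463) and -5.83 (SE 0.957, limma adjusted p 0.00151). Of the calls 84.7% were lower, against 74.2% with median log-ratio scaling and 74.1% with edgeR, which called 99 higher and 283 lower. With only the compared groups in the fit there were 0 calls at 6 h and 100 at 1 h. The 6 h count was 736 (334 higher, 402 lower), 31 and 75 without control replicates 1, 2 and 3, and 41 and 83 without mixture replicates 1 and 3.

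**Figure D3:**
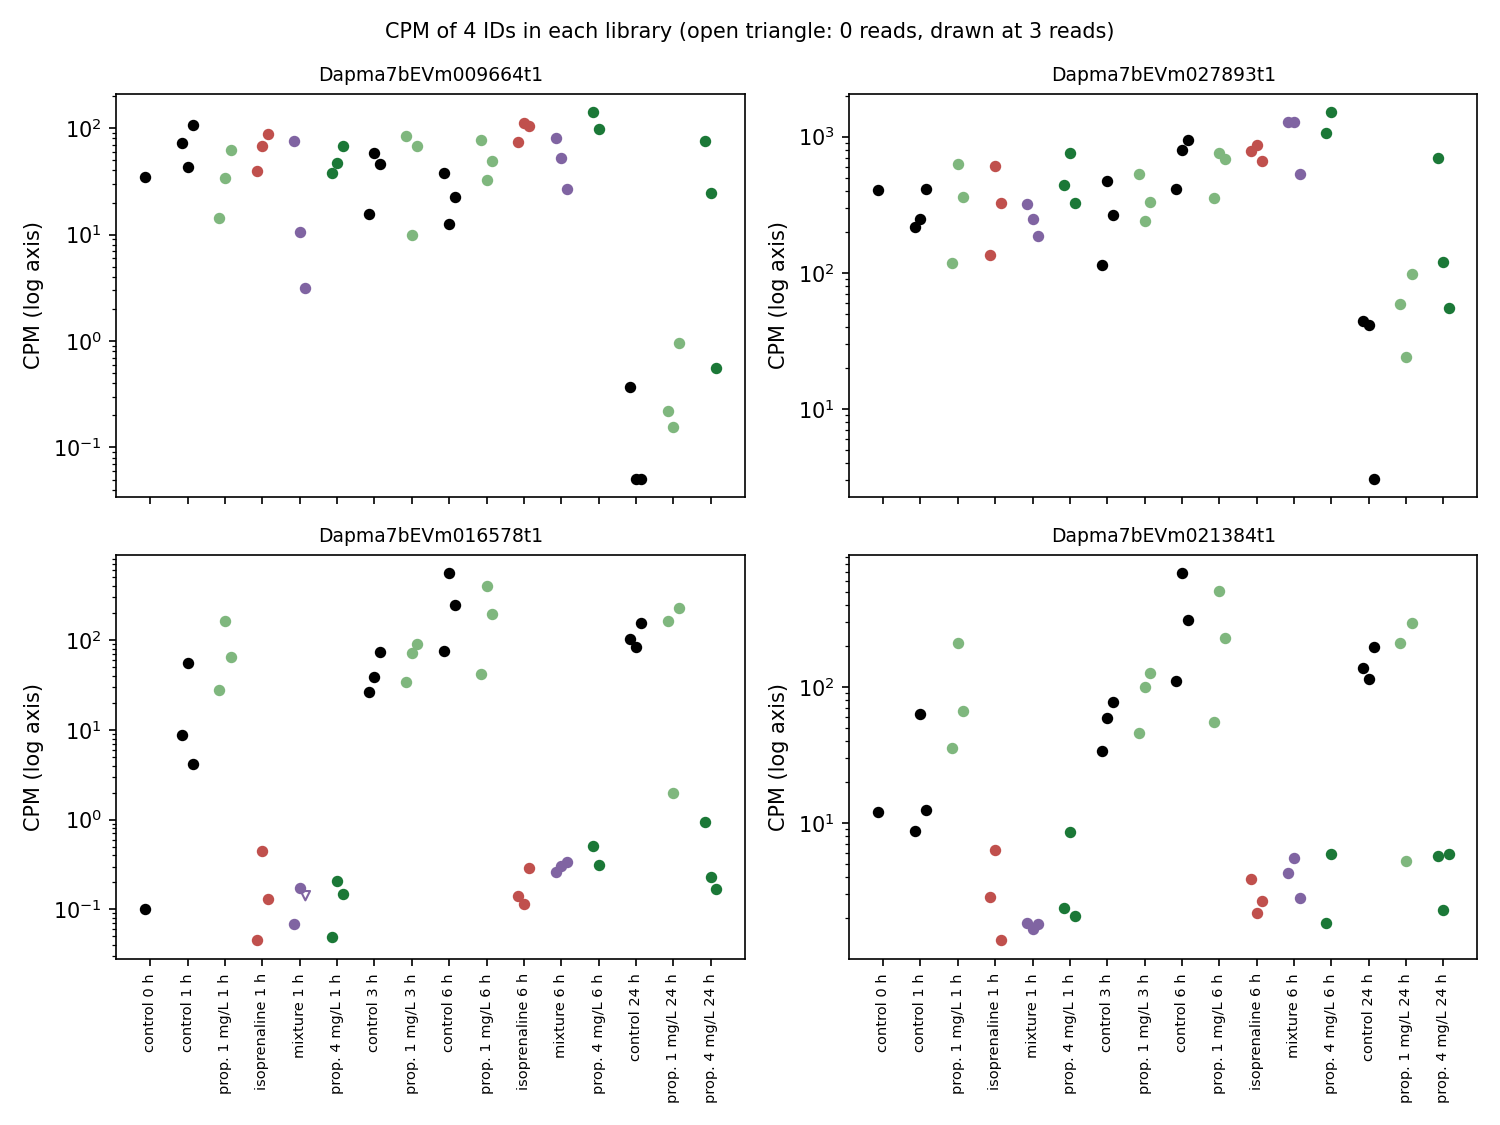
Each point is the CPM of an ID in a library, on a log axis, by exposure and hour, coloured by exposure. Dapma7bEVm016578t1 lies under 1 CPM in all libraries of isoprenaline, the mixture and propranolol 4 mg/L and in the 0 h control, and between 1.98 and 558.1 CPM in control and propranolol 1 mg/L from 1 to 24 h.

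Direct contrasts asked whether the exposures differed from each other. The mixture and isoprenaline did not differ in any ID at 1 or 6 h with limma (169 and 58 unadjusted) or edgeR (142 and 80 unadjusted). This does not show that they act alike: the median SE of a log2 difference was 0.279. The doses of propranolol differed in 4 IDs at 1 h, 726 at 6 h (25 higher at 4 mg/L, 701 lower) and 5 at 24 h. The mixture differed from propranolol 1 mg/L in 1 ID at 1 h and 166 at 6 h (36 higher, 130 lower), and isoprenaline in 4 at 1 h and 110 at 6 h (15 higher, 95 lower). Dapma7bEVm016578t1 was lower than in propranolol 1 mg/L at 1 h, by -5.89 for propranolol 4 mg/L, -5.82 for isoprenaline and -5.97 for the mixture (SE 0.999 each, limma adjusted p 0.0134, 0.0176 and 0.0253). Against control at 1 h it did not pass in any of these exposures, with log2 differences of -3.64, -3.57 and -3.72 (limma adjusted p 0.972, 1 and 0.448, edgeR 0.0683, 0.0602 and 0.0727). Each of the 3 calls was lost in 5 of 6 fits with a library left out, all but that without propranolol 1 mg/L replicate 1 (adjusted p up to 0.298, 0.304 and 0.692), and with only the compared groups in the fit (0.138, 0.392 and 0.457).

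The counts at 1 and 24 h depended on single libraries and on the groups in the fit. With only the compared groups the doses differed in 1 ID at 1 h, none of the 4 above, and in 0 at 24 h, and edgeR called 9 and 29. At 1 h they differed in 0 without replicate 2 or replicate 3 of either dose. At 24 h the count was 1, 68 and 2 without propranolol 1 mg/L replicates 1, 2 and 3, and 1, 3 and 42 without those of propranolol 4 mg/L, and it was 38 with 1 surrogate variable. For the mixture and isoprenaline against propranolol 1 mg/L at 1 h, edgeR called 17 and 9, and both had 3 calls without propranolol 1 mg/L replicate 1 and 0 without any other library.

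At 6 h the lower share of calls was 96.6% between the doses (83.2% with median log-ratio scaling, 71.2% with edgeR), 78.3% for the mixture against propranolol 1 mg/L (67.9% and 64.9%) and 86.4% for isoprenaline (82.6% and 78.7%). With only the compared groups in the fit these 3 contrasts had 0 calls at 6 h. The counts between the doses at 6 h ranged from 4 without propranolol 4 mg/L replicate 1 to 1364 without its replicate 2. Those of the mixture ranged from 7 to 211, with 21 higher and 20 lower without propranolol 1 mg/L replicate 3, and those of isoprenaline from 6 to 266 when libraries were left out in turn.

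Isoprenaline and the mixture were also set against propranolol 4 mg/L, contrasts added after seeing the data. Isoprenaline differed in 0 IDs at 1 h (40 unadjusted, edgeR 0 and 64) and 8 at 6 h, 7 of them higher in isoprenaline (edgeR 5). The mixture differed in 0 at 1 h (433 unadjusted, edgeR 0 and 539) and 0 at 6 h (1103 unadjusted, edgeR 2 and 655). The median 95% interval of a log2 difference reached 0.57 either side at 1 h and 0.637 at 6 h, so changes of that size remain open. Larger ones do too, since these intervals are not adjusted over IDs as the calls are, and many IDs vary more than the median.

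The mixture was compared with the sum of the single effects on the log2 scale. No ID departed from the sum at 1 h (167 unadjusted with limma, 207 with edgeR, 0 called by edgeR) or at 6 h (470 and 492, 0 called by edgeR). Effects were also compared between hours. No ID passed for propranolol 1 mg/L at 24 against 1 h (284 unadjusted, edgeR 0 and 243), isoprenaline at 6 against 1 h (1837, edgeR 0 and 1895) or the mixture (700, edgeR 0 and 759). For propranolol 4 mg/L at 24 against 1 h, 1 ID passed in both limma and edgeR, and at 6 against 1 h, a contrast added after seeing the data, 1 passed with limma and 0 with edgeR (1166 and 816 unadjusted). Beyond these IDs, the calls at 6 and 24 h and their near absence at 1 h are therefore not shown to differ for propranolol 4 mg/L, isoprenaline or the mixture. The median SE of these contrasts was 0.395, and 0.419 for the added one.

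Calls were shared between exposures at 6 h. Isoprenaline and propranolol 4 mg/L shared 6 higher and 202 lower IDs, against 0.0291 and 11.2 for independent lists. The mixture and propranolol 4 mg/L shared 6 and 236 (0.046 and 10.4), and isoprenaline and the mixture 19 and 194 (0.0793 and 4.12). In 100 draws with no effect, the deviations of libraries of all groups were dealt at random to the exposed and control libraries. The exposures then shared 32, 0 and 0 IDs on average, the first from 1 draw with 3195. The draws kept the sharing of controls but not the real 6 h control libraries. Covariances of the log2 changes across IDs were 0.447, 0.278 and 0.409, against simulated means of 0.104, 0.11 and 0.152 and maxima of 1.53, 0.793 and 0.906. The 3 control libraries were too few to split, so part of the excess may come from the shared controls. With only the compared groups in the fit 0 calls were shared. Propranolol 4 mg/L and the mixture then had 0 calls each, so this was fixed in advance and says nothing about the overlap. The shared counts also moved when a library was left out. Isoprenaline and propranolol 4 mg/L shared 208 IDs, but 0 without propranolol 4 mg/L replicate 1, 486 without its replicate 2, 356 and 8 without control replicates 1 and 2, and 124 with edgeR, 70 with 1 surrogate variable and 136 at a mean of at least 5 CPM. The mixture and propranolol 4 mg/L shared 242, but 1 without propranolol 4 mg/L replicate 1, 332 without its replicate 2 and 29 without control replicate 2. Isoprenaline and the mixture shared 213, but 612 without control replicate 1, 7 without control replicate 2, 75 with 1 surrogate variable and 140 at a mean of at least 5 CPM. Without control replicate 3, or any 1 isoprenaline library or mixture replicate 1 or 3 where these entered, the 3 counts were between 36 and 65. At 1 h and 24 h the exposures shared at most 2 calls.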

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

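The tests of depth, replicate number and the hour label, the count of shared calls with no library in common, the levels of shared IDs at 1 h, and the surrogate-variable tests were chosen only after the result was seen.

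The effect of propranolol 4 mg/L differed between 24 and 1 h for Dapma7bEVm001285t1, by -5.12 on the log2 scale (SE 0.75, limma adjusted p 0.00213). It was at 9.83 ± 8.71 CPM at 24 h against 211.9 ± 113 CPM in the control, and at 5.92 ± 1.08 CPM at 1 h against 3.48 ± 1.16 CPM (SD, n = 3 each). In 10 of 100 splits of the labels within each hour there were as many calls, up to 6 against 1 in the real one, so chance cannot be excluded for this count.

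The 0 h library, which no comparison used, held 6.5% of its reads on Dapma7bEVm011496t1, the most abundant ID, against 3.02 ± 1.13% in the control at 1 h (SD, n = 3). The controls at 6 and 24 h held 8.14 ± 3.46% and 8.14 ± 3.59% (SD, n = 3 each), so its share lies within the range of later controls.

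Libraries of the same group lay far apart along a common axis, which held 64.6% of the variance within groups. Abundant transcripts did not account for it through the scaling of libraries. Its share was 65.3% with the 20 most abundant IDs dropped and the rest rescaled by the median log ratio. As 20 of 19159 IDs they could hold little of the variance themselves, so this share cannot test that part. Thinning every library to the lowest total left 63.9%, but thinning itself adds counting noise, so this share cannot decide on it. The chi-square per degree of freedom between libraries of a group, 17.4 to 640.4, argues against counting noise alone. Neither bears on anything else that goes with depth. The deeper library lay higher in 67.4% of the pairs (29 of 43, exact 95% interval 51.5 to 80.9), so a tie to depth stays open. Pairs of one group share libraries, so that interval, which takes them as independent, is not exact here. Replicate number within an hour held a share of 0.682 of the variance on the axis (permutation p 0.00031, mean share of permutations 0.282), so shared preparation may contribute and cannot be told apart from an unrecorded state of the animals. No biological explanation was tested.

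Replicate 1 of propranolol 4 mg/L at 24 h scored 0.0169 on an axis running from 0 at the control 1 h mean to 1 at the control 24 h mean, where the 35 libraries at 1 to 6 h lay between -0.184 and 0.28 and the other 8 at 24 h between 0.683 and 1.07. The other 24 h libraries on the same side of the axis that divides libraries within groups scored 0.966 or more. They were control replicates 1 and 3, which help to set the score to 1, and replicate 1 of propranolol 1 mg/L (0.966). With that library alone outside the scale, the axis stays open. The other libraries of propranolol 4 mg/L at 24 h scored 0.693 and 0.817, below all 3 controls (0.867 to 1.07). The controls set the scale, so this alone does not point to a delay, and propranolol 1 mg/L replicates 2 and 3 scored 0.683 and 0.684. Both lay within the range set beforehand, but only because that took in propranolol 1 mg/L, itself an exposure. So a delay by propranolol 4 mg/L stays open. A wrong hour label is a candidate explanation that has the value it needs. No early library analysed lay in the 24 h range as a swap partner. None of the libraries was labelled replicate 3 of propranolol 4 mg/L at 6 h, so it could not be looked at as a partner. A delay in the doubted 24 h library alone stays open. Without this library the calls at 24 h numbered 26 in place of 308, and both rises missed the threshold (adjusted p 0.322 and 0.326), but the loss of the rises is not particular to it: leaving out 1 library at a time lost the call of Dapma7bEVm009664t1 in 5 of 6 fits and that of Dapma7bEVm027893t1 in 4 of 6.

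At 6 h, 175 IDs were called for isoprenaline, the mixture and propranolol 4 mg/L alike, 171 of them lower. With 1 surrogate variable 88.1% of the mixture calls and 99.9% of the propranolol 4 mg/L calls remained. That variable goes with the axis within groups in many libraries, with the sign reversed, but is not the same. Isoprenaline replicate 2 at 1 h lay at -98.09 on the axis and 0.2958 on the variable. For propranolol 4 mg/L replicate 2 at 24 h these were 81.81 and -0.2515. But control replicates 2 and 3 at 6 h lay at -93.93 and -81.72 on the axis and at 0.2306 and 0.04912 on the variable. The variable thus takes out the axis only in part, and the axis stays open for both exposures. Of the isoprenaline calls 22% remained, with a smaller median change (1.51, median SE 0.356 before, 1.15 and 0.309 after) of the same sign in 100%. That share met the bound for the axis as cause, written after the result was seen. At 6 h the isoprenaline libraries lay at 37.68 to 64.77 on the axis and the controls at -93.93 to -7.534. Exposure and axis are confounded there, so how far the axis bears on that part stays open. Shared 6 h controls as the whole cause are argued against by the libraries at 1 h, where the mean level of the 171 lower IDs was 2.1 to 2.77 (log2) in the 9 libraries of the 3 exposures and 2.88 to 4.12 in the 6 of control and propranolol 1 mg/L, a difference of -0.868 (exact two-sided permutation p 2e-04, the smallest it can give). That p takes the libraries as independent, but same-numbered control and propranolol 1 mg/L libraries at 1 h deviated together (r of 0.529, 0.22 and 0.289). Against control alone (2.88 to 3.45) the difference was -0.694 (exact permutation p 0.0045). How far shared 6 h controls add to the overlap stays open: with no library in common 5 higher and 141 lower calls were shared (146 in all, 0.0405 and 10.6 for independent lists), but control and propranolol 1 mg/L libraries of the same number at 6 h deviated together (r of 0.723, 0.74 and 0.389), and over all IDs the covariance of 0.29 lay within a simulated range (-0.857 to 0.728) too wide to decide. A separate experiment for control and propranolol 1 mg/L, the only exposures at 3 h, is confounded with the exposures and cannot be told apart: the difference at 1 h had a median ratio of 0.445 to that at 6 h, between the bounds set for it, and an effect of the exposures themselves stays open, untested.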

How the results depend on the processing

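The surrogate variable, the mean of at least 5 CPM and the counts of shared calls were chosen only after the result was seen; the other settings were planned. The setting that moved a count most differed between comparisons. The filter alternative is void, because the deposited table had already passed the filter, and the gene lists gave no value, because no ID matched a name. Without the void filter alternative, the 4 named IDs had 295 values under alternatives for 23 calls: 228 kept their direction and side of the threshold, 67 missed the threshold and 0 reversed. Changes below are for numbers of calls, within 1.5 times where not given; for each the cause was not tested. Depth limits low IDs: 3 reads stand for 0.069 to 0.22 CPM.

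With a pseudocount of 0.25, the counts moved for propranolol 1 mg/L vs control at 24 h from 3 to 0, propranolol 4 mg/L vs propranolol 1 mg/L at 1 h from 4 to 9 and propranolol 4 mg/L vs propranolol 1 mg/L at 24 h from 5 to 9. Also moved were mixture vs propranolol 1 mg/L at 1 h from 1 to 9 and isoprenaline vs propranolol 1 mg/L at 1 h from 4 to 8.

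With only the groups compared in the fit, the counts moved for propranolol 1 mg/L vs control at 24 h from 3 to 0, propranolol 4 mg/L vs control at 1 h from 2 to 0 and propranolol 4 mg/L vs control at 6 h from 754 to 0. Also moved were propranolol 4 mg/L vs control at 24 h from 308 to 6, isoprenaline vs control at 1 h from 3 to 0 and isoprenaline vs control at 6 h from 322 to 2082. Others that moved were mixture vs control at 1 h from 0 to 100, mixture vs control at 6 h from 320 to 0 and propranolol 4 mg/L vs propranolol 1 mg/L at 1 h from 4 to 1 (another ID, lower; none of the 4 remained). To these come propranolol 4 mg/L vs propranolol 1 mg/L at 6 h from 726 to 0, propranolol 4 mg/L vs propranolol 1 mg/L at 24 h from 5 to 0 and mixture vs propranolol 1 mg/L at 6 h from 166 to 0. Beside them stand isoprenaline vs propranolol 1 mg/L at 1 h from 4 to 0, isoprenaline vs propranolol 1 mg/L at 6 h from 110 to 0 and propranolol 4 mg/L effect at 24 h minus 1 h from 1 to 0. There were further moves for control 6 h vs 1 h from 1 to 752, calls shared by isoprenaline and propranolol 4 mg/L from 208 to 0 and calls shared by isoprenaline and mixture from 213 to 0. The remaining moves were calls shared by mixture and propranolol 4 mg/L from 242 to 0.

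Replicate numbers are not said to pair libraries, so the block is given as counts only. The 4 comparisons that passed the check of pairing had 0 calls with and without the block, so they cannot show whether pairing matters. Propranolol 4 mg/L at 6 h had only 2 pairs and was left out of that check, although both pairs deviated together (r of 0.716 and 0.545 with control). With the replicate block, the counts moved for propranolol 1 mg/L vs control at 24 h from 3 to 1 (another ID, higher; none of the 3 remained), propranolol 4 mg/L vs control at 1 h from 2 to 6 and propranolol 4 mg/L vs control at 6 h from 754 to 1274. Also moved were propranolol 4 mg/L vs control at 24 h from 308 to 763, isoprenaline vs control at 1 h from 3 to 6 and isoprenaline vs control at 6 h from 322 to 2482. Others that moved were mixture vs control at 6 h from 320 to 910, propranolol 4 mg/L vs propranolol 1 mg/L at 1 h from 4 to 14 and propranolol 4 mg/L vs propranolol 1 mg/L at 24 h from 5 to 26. To these come mixture vs propranolol 1 mg/L at 1 h from 1 to 19, mixture vs propranolol 1 mg/L at 6 h from 166 to 459 and isoprenaline vs propranolol 1 mg/L at 1 h from 4 to 11. Beside them stand isoprenaline vs propranolol 1 mg/L at 6 h from 110 to 401, calls shared by isoprenaline and propranolol 4 mg/L from 208 to 742 and calls shared by isoprenaline and mixture from 213 to 784. There were further moves for calls shared by mixture and propranolol 4 mg/L from 242 to 599.

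With median log-ratio scaling, the counts moved for propranolol 1 mg/L vs control at 24 h from 3 to 0, propranolol 4 mg/L vs control at 1 h from 2 to 1 and propranolol 4 mg/L vs control at 6 h from 754 to 481. Also moved were propranolol 4 mg/L vs propranolol 1 mg/L at 24 h from 5 to 8.

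With edgeR on the recovered reads, the counts moved for propranolol 1 mg/L vs control at 24 h from 3 to 0, propranolol 4 mg/L vs control at 1 h from 2 to 1 and propranolol 4 mg/L vs control at 6 h from 754 to 368. Also moved were propranolol 4 mg/L vs control at 24 h from 308 to 578, isoprenaline vs control at 1 h from 3 to 1 and propranolol 4 mg/L vs propranolol 1 mg/L at 1 h from 4 to 9. Others that moved were propranolol 4 mg/L vs propranolol 1 mg/L at 6 h from 726 to 351, propranolol 4 mg/L vs propranolol 1 mg/L at 24 h from 5 to 29 and mixture vs propranolol 1 mg/L at 1 h from 1 to 17. To these come mixture vs propranolol 1 mg/L at 6 h from 166 to 262, isoprenaline vs propranolol 1 mg/L at 1 h from 4 to 9 and calls shared by isoprenaline and propranolol 4 mg/L from 208 to 124.

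With 1 surrogate variable, the counts moved for propranolol 4 mg/L vs control at 1 h from 2 to 4, propranolol 4 mg/L vs control at 24 h from 308 to 924 and isoprenaline vs control at 1 h from 3 to 6. Also moved were isoprenaline vs control at 6 h from 322 to 75, mixture vs control at 1 h from 0 to 4 and propranolol 4 mg/L vs propranolol 1 mg/L at 6 h from 726 to 1238. Others that moved were propranolol 4 mg/L vs propranolol 1 mg/L at 24 h from 5 to 38, mixture vs propranolol 1 mg/L at 1 h from 1 to 7 and mixture vs propranolol 1 mg/L at 6 h from 166 to 348. To these come isoprenaline vs propranolol 1 mg/L at 1 h from 4 to 9, isoprenaline vs propranolol 1 mg/L at 6 h from 110 to 44 and control 24 h vs 1 h from 2466 to 5177. Beside them stand calls shared by isoprenaline and propranolol 4 mg/L from 208 to 70 and calls shared by isoprenaline and mixture from 213 to 75.

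With a mean of at least 5 CPM, the counts moved for propranolol 1 mg/L vs control at 24 h from 3 to 0, isoprenaline vs control at 6 h from 322 to 187 and isoprenaline vs propranolol 1 mg/L at 6 h from 110 to 66. Also moved were calls shared by isoprenaline and propranolol 4 mg/L from 208 to 136 and calls shared by isoprenaline and mixture from 213 to 140.

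Leaving out 1 library at a time gave counts of 0 to 3 for propranolol 1 mg/L vs control at 6 h, 0 to 5 for propranolol 1 mg/L vs control at 24 h and 0 to 1 for propranolol 4 mg/L vs control at 1 h. It gave 2 to 1938 for propranolol 4 mg/L vs control at 6 h, 26 to 605 for propranolol 4 mg/L vs control at 24 h and 0 to 1 for isoprenaline vs control at 1 h. The range was 8 to 1369 for isoprenaline vs control at 6 h, 31 to 736 for mixture vs control at 6 h and 0 to 5 for propranolol 4 mg/L vs propranolol 1 mg/L at 1 h. It gave 4 to 1364 for propranolol 4 mg/L vs propranolol 1 mg/L at 6 h, 1 to 68 for propranolol 4 mg/L vs propranolol 1 mg/L at 24 h and 0 to 3 for mixture vs propranolol 1 mg/L at 1 h. The range was 7 to 211 for mixture vs propranolol 1 mg/L at 6 h, 0 to 3 for isoprenaline vs propranolol 1 mg/L at 1 h and 6 to 266 for isoprenaline vs propranolol 1 mg/L at 6 h. It gave 0 to 2 for mixture minus sum of single effects at 6 h, 0 to 2 for propranolol 1 mg/L effect at 24 h minus 1 h and 1 to 2 for propranolol 4 mg/L effect at 24 h minus 1 h. The range was 0 to 69 for control 6 h vs 1 h, 810 to 2319 for control 24 h vs 1 h and 0 to 486 for calls shared by isoprenaline and propranolol 4 mg/L. It gave 7 to 612 for calls shared by isoprenaline and mixture and 1 to 332 for calls shared by mixture and propranolol 4 mg/L. Where propranolol 4 mg/L at 6 h was left with 1 library, that library was assumed to vary like the other groups.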

Other observations

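The contrast of exposure sets was chosen only after the shared calls were seen; the splits were planned.

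The 171 IDs lower in all 3 exposures at 6 h had a median level of 4.28 (log2) in the control and 3.93 in propranolol 1 mg/L at 6 h, against 2.08 in isoprenaline, 2.18 in the mixture and 2.01 in propranolol 4 mg/L. At 1 h the medians were 3.07, 3.50, 2.46, 2.21 and 2.37 in the same order, and at 0 h the control library had 3.23. At 24 h they were 4.13 in the control, 3.74 in propranolol 1 mg/L and 2.40 in propranolol 4 mg/L. By library, the mean over these IDs in place of the median was 4.13, 2.74 and 3.95 for propranolol 1 mg/L replicates 1 to 3. It was 2.31 to 2.74 for propranolol 4 mg/L and 3.79 to 4.13 for the control. Dapma7bEVm016578t1 was at 163.3, 1.98 and 225.6 CPM in the same 3 propranolol 1 mg/L libraries. So replicate 2 of propranolol 1 mg/L at 24 h lay with propranolol 4 mg/L on these values. The contrast of these 3 exposures with control and propranolol 1 mg/L had 59 calls at 1 h (19 higher, 40 lower) and 2295 at 6 h (388 higher, 1907 lower). With edgeR it had 93 and 2660. Of the 175 IDs called in all 3 exposures at 6 h, 173 had the same sign at 1 h.

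Dapma7bEVm015017t1 was at 96.89 CPM at 0 h (0.00969% of the reads), and within propranolol 4 mg/L at 24 h it ran from 124.4 to 46070 CPM. The spread was also wide without exposure, from 146.8 to 22430 CPM within the control at 24 h. Not every group spread so far: the mixture at 1 h ran from 24620 to 32470 CPM.

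Other splits of the same libraries were counted for 26 comparisons of groups of at least 3. With 2 groups of 3 there are 10 splits, too few for a share under 0.05. For propranolol 4 mg/L against control at 24 h the real split had 308 calls and the highest other 10, for isoprenaline at 6 h 322 and 0, for the mixture at 6 h 320 and 0, for the mixture against propranolol 1 mg/L at 6 h 166 and 0, for isoprenaline against it 110 and 0, and for the control at 24 against 1 h 2466 and 40. In each of these 1 of the 10 splits, the real one, had as many calls. The same 1 of 10 held at 1 h for propranolol 4 mg/L (2 against 0) and isoprenaline (3 against 0) with control, and for propranolol 4 mg/L (4 against 0), the mixture (1 against 0) and isoprenaline (4 against 3) with propranolol 1 mg/L.

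In other comparisons, other splits gave as many calls. For propranolol 1 mg/L against control at 24 h, 3 of 10 splits had 3 or more, up to 188. Between the doses at 24 h it was 4 of 10, up to 165 against 5, and for the control at 6 against 1 h 2 of 10, up to 2 against 1. Where the real split had 0 calls, all 10 of 10 had at least as many by construction, which says nothing about chance: propranolol 1 mg/L at 1, 3 and 6 h (highest other 0, 1 and 80), the mixture against control at 1 h (0), and the mixture against isoprenaline at 1 and 6 h (0 and 0).

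The contrasts of 4 groups used 100 splits. The real count was 0 for the mixture against the sum of single effects at 1 and 6 h (highest other 0 and 600), and for the difference between hours of propranolol 1 mg/L (256), isoprenaline (463) and the mixture (146), so all 100 of 100 had at least as many by construction and nothing follows about chance. Splits with many times the real count point to a structure of the libraries, and since they exchange exposed and unexposed libraries, differences between exposures can be part of it.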
